A study of Mus musculus with 4 samples.

How the data were processed

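ATAC-seq was carried out on HFSC sorted by flow cytometry as negative for Ly-6A/E and positive for CD34 and a marker that the labels give as CD45f, with 2 samples per genotype. Which protein CD45f stands for is not stated, so which cells this marker kept is not known here. Per the submitters' processing notes the tools were FastQC, cutadapt 2.9, Bowtie2, Genrich 0.6, deepTools 3.4.2 and ChIPseeker 1.24.0, and the build was mm10. The role of each tool, the settings of the peak calling and the handling of multiply mapped and duplicate reads are not given in the sources used here, nor is any shift of the reads for the Tn5 cut. Per the labels, each deposited list belongs to both replicates of 1 genotype, so peaks were used as pooled lists.

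The deposited files give each peak's position and a score, which is the authors' own value per peak, a whole number of at least 50. The columns for signal, p-value and q-value hold 0 in all 486180 Irx5KO and 499794 WT entries of the deposited lists. Scores were therefore used to rank and filter peaks within a list, and score values were never compared between lists. Gene-end counts after a score threshold did set the upper ranks of both lists against each other. Peak borders lay on a 10 bp grid and the smallest width was 200 bp. The peaks on unplaced contigs, 1188 in Irx5KO and 1733 in WT, stayed out of the comparisons.

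Gene positions came from a RefSeq gene table of GRCm38, the same assembly as mm10, with 21887 protein-coding genes on the standard chromosomes. Some of these genes, such as Csprs and Ren2 at the start of chromosome 1, had no peak assigned in either list. Whether the positions of such genes hold on mm10 was not checked, and they count among genes without a gene-end peak. The table gives gene spans without strand, exons or transcript starts. Promoters were therefore replaced by windows of 1000 bp on each side of either gene end, and exons and introns were not told apart. Motif content was planned but not run, since no genome sequence was used here. The planned ranking by signal was replaced by the score. Of 276 entries in the 16 gene lists, 275 were matched by symbol or synonym; Krt85 was not.

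Peaks were called shared on an overlap of at least 1 bp and otherwise listed in 1 genotype only, which says nothing on loss or gain, since a list depends on depth and threshold. The overlap expected by chance came from 20 shuffles within chromosomes. For each gene list the share of Irx5KO-only among genotype-only peaks was placed among 10000 random lists matched gene by gene on deciles of peak number. Percentiles at or under 2.5, or at or above 97.5, were taken as calls, with 16 lists examined, as a description of these lists and not as p-values. Gene lists, the design and the main alternatives were fixed before the data were examined.

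Named genes followed a rule fixed in advance. It took Irx5, Fgf18 and Brca1, up to 4 genes per list by first place in the list (gene-end peak in 1 genotype only, then in both), the genes nearest to the 10 highest-ranked genotype-only peaks of each list within 50000 bp, and the 5 genes with the largest excess in each direction. Some genes that this rule takes are not reported here.

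The code was tested on simulated data. For the comparison of Irx5KO-only with WT-only peaks in lists of 22 out of 21887 genes, a planted share of 60% was called in 87 of 100 lists and a planted share of 70% in 100 of 100. With no planted shift 1 of 100 lists was called. In these simulations the genotype-only peaks of each gene were drawn independently, with 1 common share outside the planted list. Real shares varied between gene families, from 25.65% for Esp to 71.2% for Arid. The rates found by simulation therefore need not hold for the real lists. For gene-end peaks, all 200 planted genes out of 21887 were recovered. Shared peak numbers were equal to those of bedtools 2.31.1 in both lists. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9. Alternatives changed the score threshold, the overlap rule, the gene-end window, the distance of assignment and the chromosomes. Under the score thresholds, peaks were called shared against the whole other list, whereas gene-end peaks were compared between both lists after the threshold. Added after the data were seen were a limit of 2000 bp on peak width, equal list lengths, other matchings of the random lists and the HFSC identity list without Tcf7l1.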

Results

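Accessible chromatin was profiled by ATAC-seq, in which the transposase Tn5 cuts and tags open DNA, in hair follicle stem cells (HFSC) sorted from mouse skin. HFSC rest in the bulge of the follicle and start each new cycle of hair growth. The 4 samples were 2 replicates labelled Irx5KO and 2 labelled WT. Irx5 encodes a homeodomain transcription factor of the Iroquois family. The series title names DNA damage repair and HFSC activation as the processes under study. The deposited data were 1 pooled peak list per genotype, made from both replicates, so no spread between replicates could be computed and no test between genotypes was run. Every interval given is a 95% Wilson interval for counting error only. Read depth per sample was not given in the lists.

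The lists held 484992 peaks for Irx5KO and 498061 for WT on the 21 standard chromosomes of mm10. Median peak width was 410 bp in Irx5KO and 400 bp in WT. The peaks covered 453.8 Mb and 465.3 Mb, of which 399.4 Mb was common to both lists. Scores were the authors' own and were used only to rank peaks within a list.

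At the targeted gene, Irx5 (chromosome 8, 92357796 to 92361456), the Irx5KO list held more peaks than the WT list. Within 10 kb of the gene the Irx5KO list held 13 peaks, of which 5 overlapped a WT peak and 8 did not. The WT list held 5 peaks there, and all 5 overlapped an Irx5KO peak. Inside the gene body lay 4 Irx5KO peaks and 2 WT peaks. Both lists had a peak over the lower end of the gene, from 92356871 to 92358180 in Irx5KO and from 92357211 to 92357990 in WT. The labels do not describe the allele, so listed peaks within Irx5 do not check the genotype labels. In the upper 50% of each list by score, the Irx5 locus kept 3 peaks in each genotype.

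Fgf18 encodes a growth factor that holds HFSC in the resting phase. Around Fgf18 (chromosome 11, 33116970 to 33147400) the Irx5KO list held 6 peaks and the WT list 5, with 3 of each overlapping the other list. Over the wider region assigned to Fgf18, 7 peaks were listed in Irx5KO only and 3 in WT only. Brca1 encodes a protein of homologous recombination. Around Brca1 (chromosome 11, 101488761 to 101551955) the Irx5KO list held 4 peaks, all of them shared, and the WT list 6, of which 1 was listed in WT only.

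**Figure D1:**
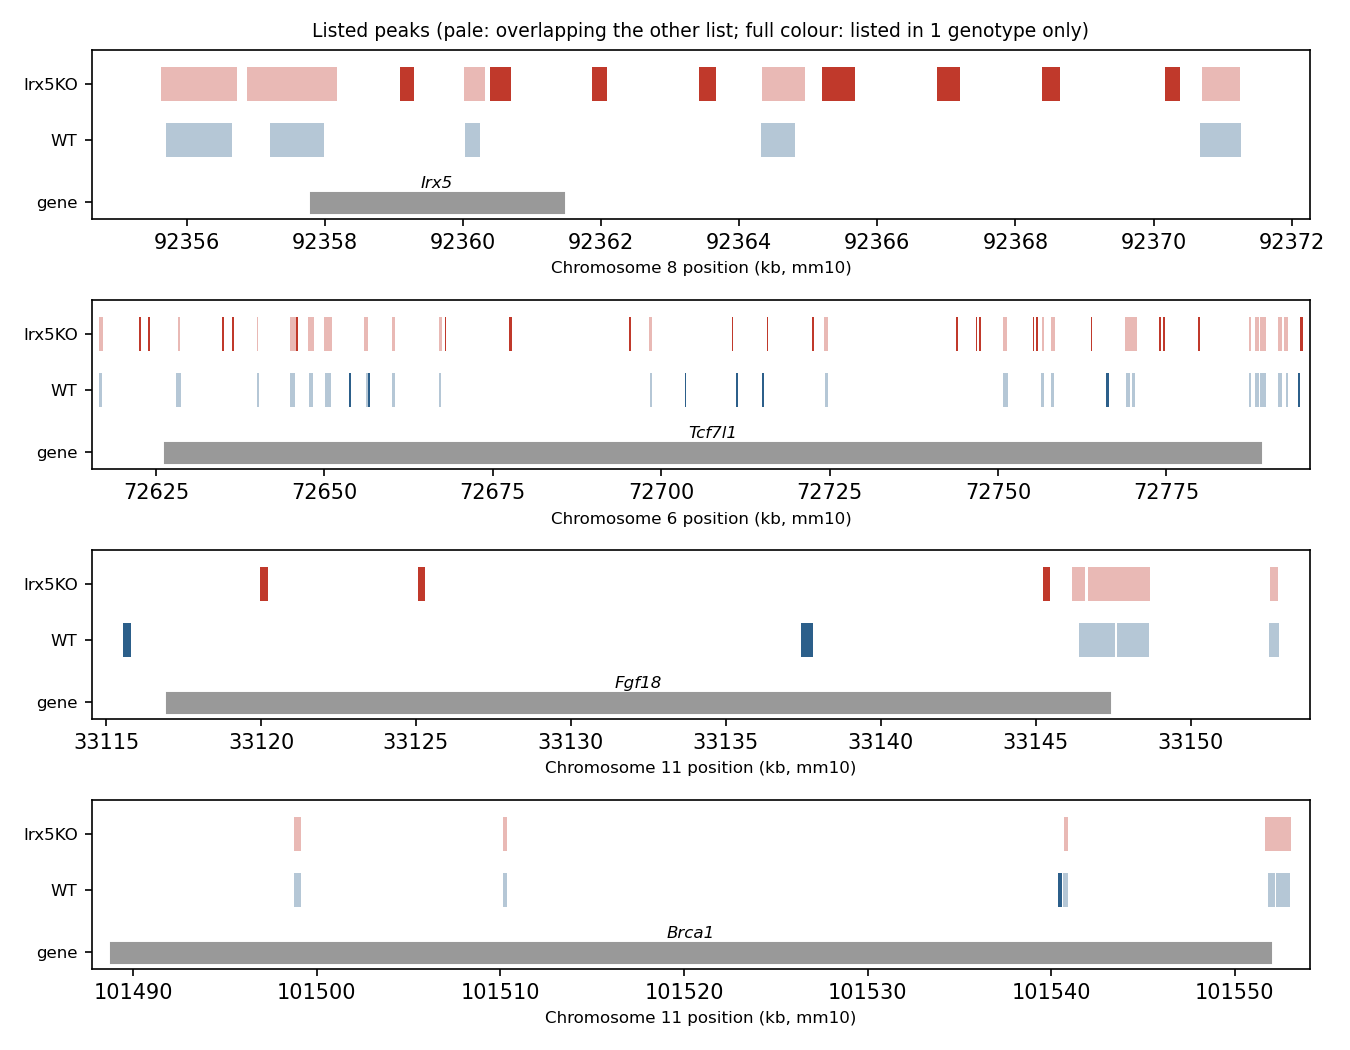
Peaks listed in Irx5KO (red) and WT (blue) around Irx5, Tcf7l1, Fgf18 and Brca1, with position in kb of mm10 on the horizontal axis and the annotated gene span in grey. Pale boxes overlap a peak of the other list and full-colour boxes do not; at Irx5 all 8 genotype-only peaks are in Irx5KO.

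Most listed regions were common to both genotypes. Of the Irx5KO peaks, 78.2% (78.05 to 78.3) overlapped a WT peak by at least 1 bp, and 73.4% (73.3 to 73.5) of the WT peaks overlapped an Irx5KO peak. Peaks placed at random within chromosomes overlapped the other list in 28.2% and 27.3% of cases. This left 105910 peaks listed in Irx5KO only and 132587 listed in WT only. Genotype-only peaks had low scores within their own lists, with medians of 94 against 262 for shared peaks in Irx5KO and 93 against 267 in WT. In the lowest decile by score 22.3% of Irx5KO peaks and 18.1% of WT peaks were shared, and in the highest decile 99.8% and 99.9% were.

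Peaks listed in Irx5KO only lay at gene ends more often than peaks listed in WT only. A gene end here is a window of 1000 bp on each side of either annotated end of a protein-coding gene. For shares of peaks, a peak counted where its midpoint lay in such a window. For counts of genes, any overlap of a peak with the window counted. A gene with a gene-end peak in 1 genotype only had no peak of the other list in its windows. Its own gene-end peak could still overlap a peak of the other list outside them. The share was 4.46% (4.34 to 4.59) of Irx5KO-only peaks and 2.86% (2.77 to 2.95) of WT-only peaks. Gene bodies held 37.0% of Irx5KO-only peaks (36.7 to 37.2) and 32.6% of WT-only peaks (32.4 to 32.9). In the upper 50% of each list by score the gene-end shares were 1.73% (1.48 to 2.04) and 1.46% (1.25 to 1.69), with overlapping intervals. Among the 50000 highest-scored peaks they were 0.943% (0.167 to 5.15) and 5.09% (1.74 to 13.9), from 1 of 106 and 3 of 59 peaks, too few to show an order. Of all peaks 4.64% in Irx5KO and 4.45% in WT lay at gene ends, and of shared peaks 4.68% and 5.03%. A difference between library preparations cannot be told apart from an effect of genotype in these shares.

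In both lists the highest-scored peaks lay less often at gene ends, by midpoint, than the others. A wide peak that reaches a gene end can have its midpoint outside the window. Median width in the highest decile was 1880 bp in Irx5KO and 2060 bp in WT. The gene-end share in the highest decile was 2.66% (2.52 to 2.80) in Irx5KO and 1.195% (1.103 to 1.29) in WT, against 4.64% and 4.45% of all peaks. The median score of gene-end peaks was 0.767 times that of peaks over 50000 bp from any gene end in Irx5KO and 0.681 times in WT. Among peaks up to 2000 bp wide these ratios were 0.8195 and 0.7435.

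**Figure D2:**
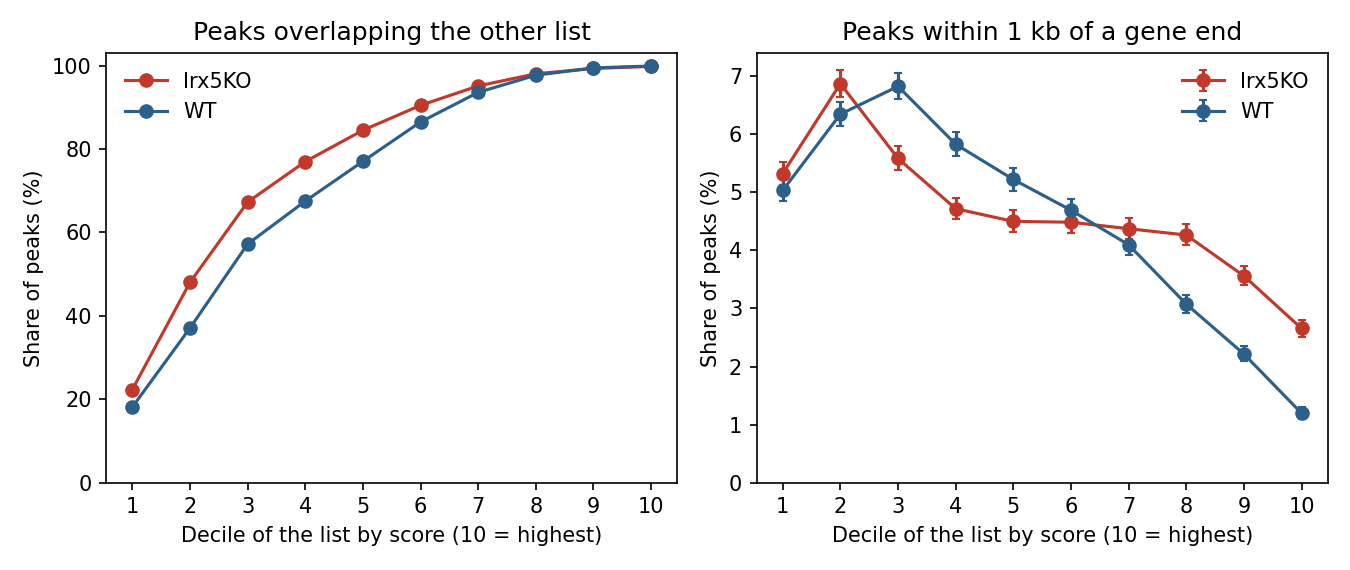
Share of peaks that overlap the other list (left, percent) by decile of each list by score, for Irx5KO (red) and WT (blue). At right, the share with its midpoint within 1 kb of a gene end (percent, with 95% Wilson intervals). Overlap rises from 22.3% and 18.1% in the lowest decile to 99.8% and 99.9% in the highest, where the gene-end share is 2.66% and 1.195%.

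Of 21887 protein-coding genes, 16457 had a gene-end peak in both genotypes, 1329 in Irx5KO only, 874 in WT only and 3227 in neither. In the upper 50% of each list by score 2584 genes had one in Irx5KO only and 576 in WT only, where the upper 50% of both lists were set against each other, and with windows of 3000 bp 786 and 542 did. Gene-end peaks were also frequent in gene families of the sensory organs, planned as a background of genes that skin cells do not use. Among 1463 olfactory and vomeronasal receptor genes, which serve smell and pheromone sensing, 69.0% (66.6 to 71.3) had one in Irx5KO and 73.8% (71.5 to 76.0) in WT. The other coding genes had one in 82.1% and 79.6% of cases. In the upper 50% of each list by score the receptor genes fell to 28.0% and 31.5%, against 53.7% and 43.6% of the others. In these upper ranks the lists thus differed as a whole, with Irx5KO higher at the other genes and WT higher at the receptor genes. The cause of that difference was not tested.

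The HFSC identity genes carried more Irx5KO-only than WT-only peaks. Peaks were assigned to the protein-coding gene with the nearest end within 50000 bp. The 22 genes of the list held 132 Irx5KO-only and 66 WT-only peaks, an Irx5KO-only share of 66.7% (59.8 to 72.9), against 48.0% (47.7 to 48.3) over all coding genes. That share was at the 100th percentile of 10000 random lists matched on peak number. Of the members, 18 had more Irx5KO-only peaks, 3 had more WT-only peaks and 1 had equal numbers. The housekeeping list, fixed as a control, had a like share of 65.9% (51.1 to 78.1) from 29 and 15 peaks, at percentile 96.7. In the upper 50% of each list by score the HFSC identity genes kept 7 Irx5KO-only and 6 WT-only peaks, at percentile 72.0, so the call was lost there.

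Named by the rule set in advance, Foxp1, a transcription factor of HFSC quiescence, had a gene-end peak in Irx5KO only, and 4 and 3 genotype-only peaks in Irx5KO and WT. Cd34, which encodes a surface marker sorted for, had 2 and 4, the bulge keratin gene Krt15 had 2 and 0, and the basal keratin gene Krt5 had 0 and 2. The members with the largest excess, chosen after their values were seen, were Tcf7l1 with 18 and 4, Sfrp1 with 14 and 6, and Runx1 with 12 and 5. Tcf7l1 and Runx1 encode transcription factors and Sfrp1 a secreted WNT antagonist. Without Tcf7l1 the list held 114 and 62 peaks, a share of 64.8% (57.5 to 71.5), again at percentile 100.

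For genes of anagen activation, WNT and SHH signalling, the share was 54.7% (49.2 to 60.0), from 176 Irx5KO-only and 146 WT-only peaks in 30 genes. The percentile of 97.55 lay at the edge of the limit for a call and fell under it in 6 of 8 alternatives. Wnt10b, Rspo3 and Fgf10 had a gene-end peak in Irx5KO only and Shh had one in WT only. Over their wider assigned regions Fgf10 had 4 Irx5KO-only and 19 WT-only peaks and Rspo3 had 9 and 17. The list of HFSC quiescence and BMP-FGF18 signalling held 71 and 62 peaks, at percentile 75.8. It shares Nfatc1, Foxc1 and Foxp1 with the identity list. Among its members Fgfr3 had 6 and 0 and Bmp4 had 4 and 6.

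Neither list of DNA repair genes was called. The 32 genes of homologous recombination and Fanconi anaemia repair had a gene-end peak in both genotypes, all 32 of them. They held 74 Irx5KO-only and 74 WT-only peaks, a share of 50% (42.05 to 57.95), at percentile 60.4. In the upper 50% of each list by score they held 2 and 9, a share of 18.2% (5.14 to 47.7), at percentile 2.83, near the lower limit for a call. Brca1 had 0 and 1, Brca2 had 0 and 0, and Rad51b had 4 and 5. The genes of end joining and double-strand break signalling held 59 and 62 peaks, at percentile 37.2. Within that list Clspn had a gene-end peak in Irx5KO only, and Xrcc4 had 6 and 16 genotype-only peaks, Xrcc5 had 5 and 2 and Lig4 had 2 and 2. The cell cycle and replication list held 67 and 66 peaks, at percentile 44.2. The gene ends of Ccnd1 and Ccnd3, which encode D-type cyclins, had peaks in Irx5KO only, while those of Ccna2 and Ccnb1 had peaks in both.

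The Iroquois family held 43 Irx5KO-only and 28 WT-only peaks, at percentile 92.5. Irx5 itself gave 11 and 3 of these, Irx1 gave 7 and 5, Irx2 gave 5 and 5, Irx3 gave 6 and 2, and Irx4 gave 8 and 8.

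Markers of other skin cell types were counted in the same way. The interfollicular and upper-follicle epidermis list held 27 and 26 peaks (percentile 53.8), with gene-end peaks at Krt1, Krt10 and Krt79 in Irx5KO only and at Sbsn in WT only. In that list Ly6a, which encodes the marker sorted against and was chosen after its values were seen, had 0 Irx5KO-only and 4 WT-only peaks, with a gene-end peak in both. The hair shaft and inner root sheath list held 44 and 25 (percentile 93.8), with Krt75, Foxn1, Hoxc13 and Dlx3 marked in both genotypes and 7 of its 13 matched genes in neither. The sebaceous list held 25 and 31 (percentile 28.7), with Scd1, Elovl3, Awat2 and Mgst1 marked in both. The fibroblast and dermal papilla list held 54 and 61 (percentile 41.0), with Pdgfra marked in Irx5KO only and Col1a1, Col1a2 and Vcan in both. The haematopoietic and immune list held 22 and 20 (percentile 51.7), with Ptprc and Cd74 marked in WT only, Cd4 in Irx5KO only, Cd8a in both and 5 of its 12 genes in neither. The melanocyte list held 42 and 29 (percentile 96.1), with Mlana, Tyr and Kit marked in WT only and Pmel in both. The endothelial list held 44 and 38 (percentile 82.0), with Cdh5 marked in WT only, Erg in Irx5KO only and Kdr and Tek in both. The nerve, Schwann and muscle list held 19 and 9 (percentile 87.7), with Ngfr and Des marked in Irx5KO only. In the housekeeping list Actb was marked in Irx5KO only, and Gapdh, Hprt and Tbp in both.

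**Figure D3:**
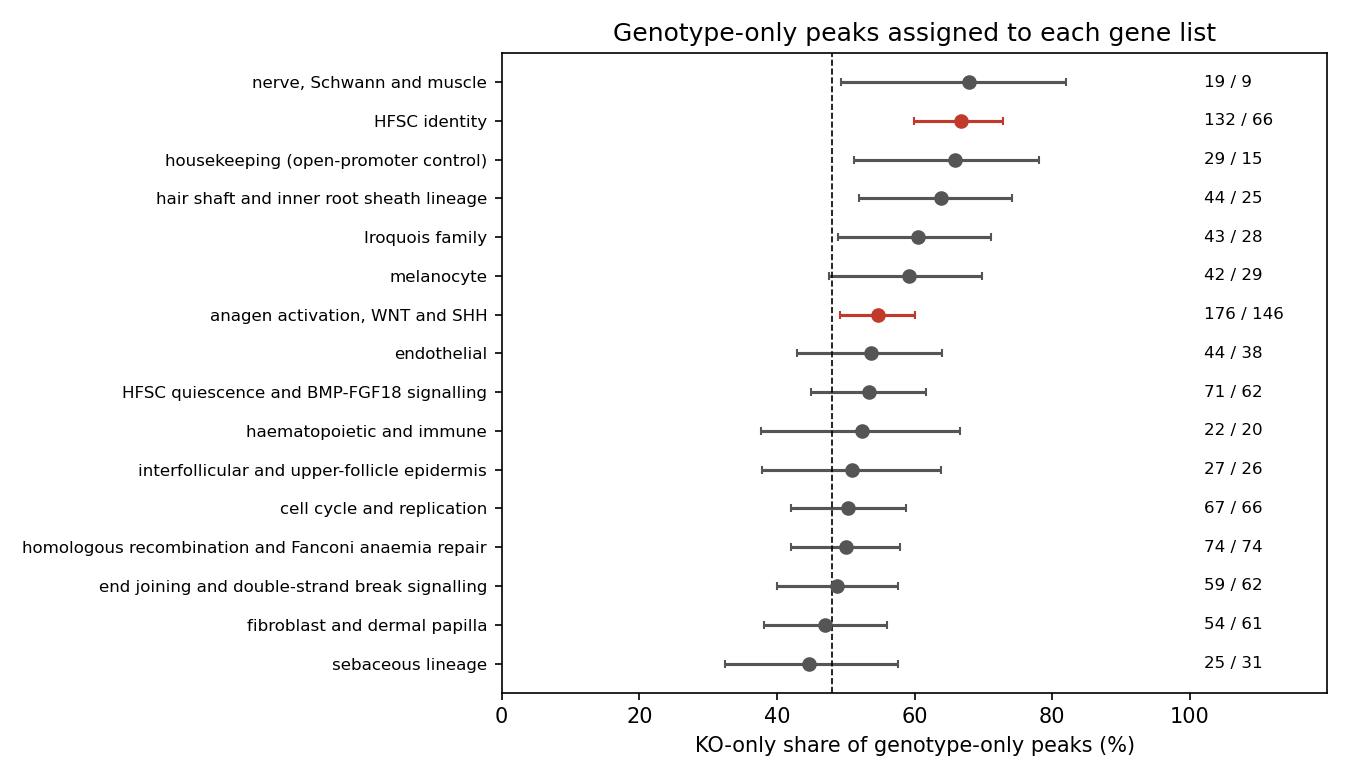
Irx5KO-only share of the genotype-only peaks assigned to each of the 16 gene lists, in percent on the horizontal axis, with 95% Wilson intervals and the Irx5KO-only and WT-only peak numbers at the right. The dashed line is the share over all coding genes (48.0%), and red marks the lists that were called, HFSC identity at 66.7% and anagen activation at 54.7%.

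Single genes with the largest excess were named by count. More Irx5KO-only than WT-only peaks were assigned to Cr2 (26 and 4), Ptprf (23 and 2), Npas2 (17 and 1), Grm4 (26 and 11) and Kat2b (18 and 4). Npas2, a clock transcription factor, also had gene-end peaks in Irx5KO only. More WT-only peaks were assigned to Defb7 (3 and 30), Cyp3a25 (4 and 29), Cyp2a22 (2 and 25), Duxbl3 (3 and 26) and Duxbl1 (1 and 23), which belong to families of similar neighbouring genes. Reads shared between such copies could make their counts uncertain, which was not tested.

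The highest-scored Irx5KO-only peak lay in Nudt14 (chromosome 12, 112934301 to 112934500), and the next were nearest to Cd44, Mkx, Camsap2, Trub1, 4930519G04Rik, Olfr854, Ice2, Zfp143 and Rspo2. The peaks at Nudt14, Mkx and Camsap2 had the smallest width, 200 bp, whereas that at Trub1 was 820 bp wide. The Nudt14 peak had a score of 15791, where the highest decile of the Irx5KO list began at 593. The peak assigned to Cd44, which encodes a hyaluronan receptor, lay inside the gene (chromosome 2, 102829281 to 102829490), 18.3 kb from its nearest end. The highest-scored WT-only peak lay 7.36 kb from Cyp2b19 (chromosome 7, 26779881 to 26780090), and others among the highest-scored were nearest to Ttll10, Ceacam2, Ktn1, Tpd52l1, Cacna1a, Tmco5b and Abi3bp. The Cyp2b19 peak was 210 bp wide with a score of 19348, where the highest decile of the WT list began at 620. What gave such narrow peaks these scores was not tested.

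A few stretches of 50 kb or more formed a single peak in 1 list and were covered by less than 50% in the other. In WT a single peak of 137.1 kb lay inside Dock2 (chromosome 11, 34545121 to 34682200), which encodes a guanine nucleotide exchange factor of white blood cells. The Irx5KO list covered 0.394% of it. A WT peak of 509.9 kb on chromosome 5 (15047081 to 15556980) was covered to 22.5% by the Irx5KO list. In Irx5KO a peak of 278 kb on chromosome 8 (55111621 to 55389600) was covered to 20.1% by WT, and a peak of 140.3 kb on chromosome X (31010671 to 31150990) to 34.8%. A WT peak of 60.5 kb on chromosome Y (16539311 to 16599820) had no Irx5KO peak. Of peaks of 50 kb or more, these were 2 of 183 in Irx5KO and 3 of 197 in WT.

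**Figure D4:**
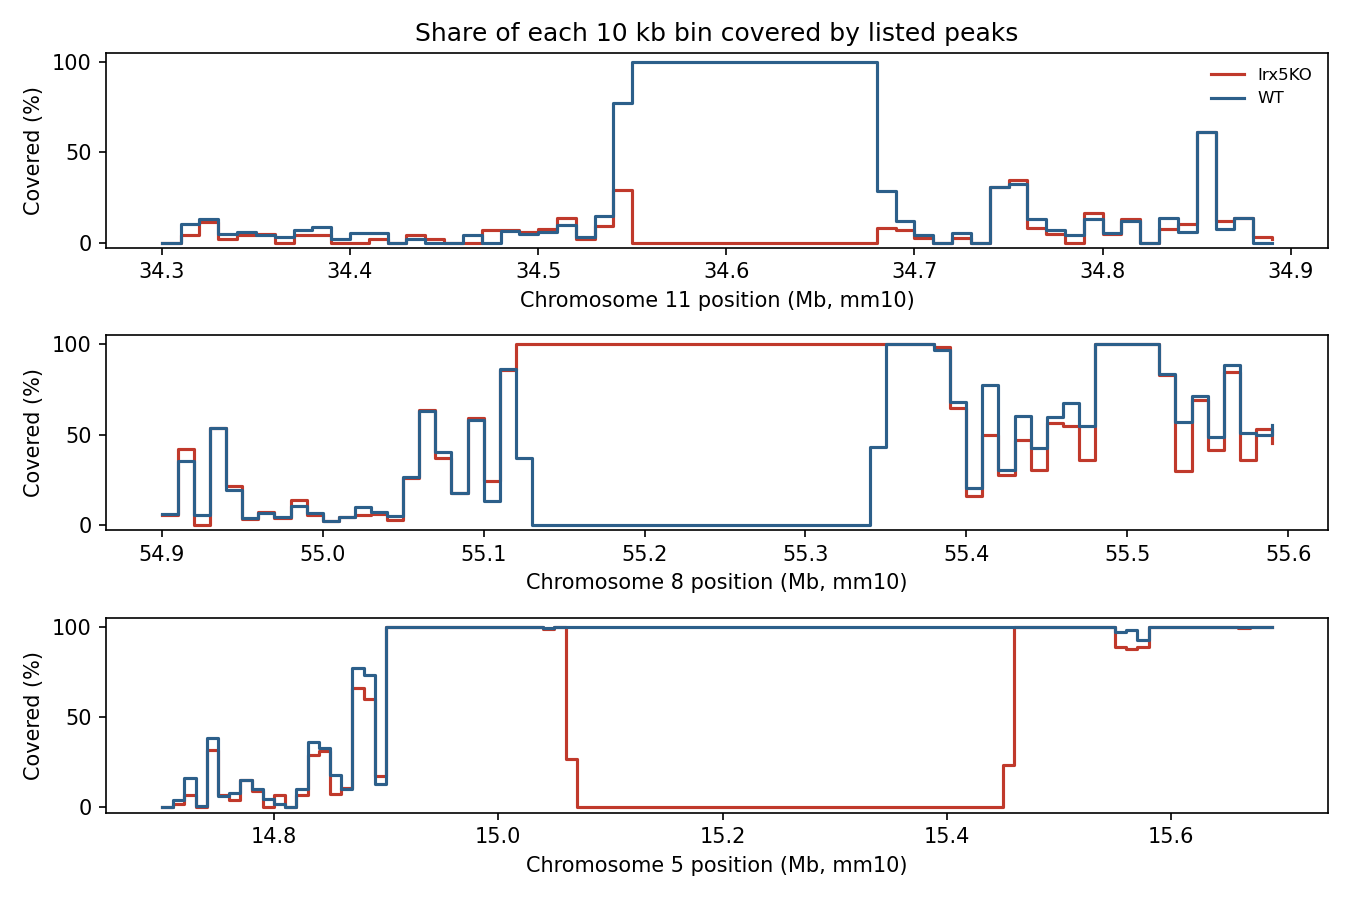
Share of each 10 kb bin covered by listed peaks, in percent, along chromosomes 11, 8 and 5 (position in Mb of mm10), for Irx5KO (red) and WT (blue). The WT list covers the Dock2 stretch on chromosome 11 and the stretch on chromosome 5, and the Irx5KO list that on chromosome 8, where the other list covers 0.394%, 22.5% and 20.1% of the whole peak.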

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

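Of the tests in this part, that of the HFSC identity list under matching on gene-end activity and the 2 on the chromosome 5 cluster were set before their results were seen, and all others were chosen after.

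Peaks on unplaced contigs entered no comparison. Among 16 contigs with at least 20 peaks in both lists, 5 contigs of chromosome 5 were covered more in Irx5KO than in the WT control by over 5 percentage points, and 6 other contigs were covered less by over 5. The differences were 9.17 points for GL456354, 9.23 for JH584296, 8.34 for JH584297, 12.6 for JH584298 and 18.0 for JH584299.

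The excess of Irx5KO-only peaks at HFSC identity genes was weighed first. For a signal gain shared by all genes of like gene-end activity, the percentile stayed at 100 under matching on that activity. This argues only against a gain that follows the rank of the best gene-end peak, in 5 groups from these same lists. Runx1 and Trp63 had no gene-end peak, and the peaks counted lay up to 50000 bp from a gene end. A gain at active regions that gene ends do not show therefore stays open. The housekeeping list had a like share of 65.9%, at percentile 95.8 under that matching. Other cell types in the WT sort stay open: of 48 markers in 5 non-epithelial lists, 6 had a gene-end peak in WT only, or 12.5% (5.86 to 24.7) against 3.99% of all genes, at percentile 99.1 of matched random lists, as such cells would give, and 5 had one in Irx5KO only, at percentile 89.5. Such cells would also lower the Irx5KO-only share of peaks at these markers, but it was 53.55% (48.2 to 58.8) against 48.0% over all genes, at percentile 93.5, with 67.9% (49.3 to 82.1) for nerve, 59.15% (47.5 to 69.8) for melanocyte, 53.7% (42.9 to 64.0) for endothelial, 52.4% (37.7 to 66.6) for immune and 47.0% (38.1 to 56.0) for fibroblast markers, and the sort for CD34 and against Ly-6A/E would leave out part of these cell types, with no purity given. Epithelial cells other than HFSC were not weighed and stay open in both sorts. Of 14 interfollicular and upper-follicle markers, 3 had a gene-end peak in Irx5KO only and 1 in WT only, and Ly6a had 0 and 4 genotype-only peaks. With 1 list per genotype, a difference between library preparations cannot be told apart from an effect of genotype, and a biological difference at these genes stays open as a hypothesis that rests on low-scored peaks.

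The second pattern was that the highest-scored peaks lay away from gene ends and that widths gathered between 6000 and 6500 bp, with 7154 such peaks in Irx5KO and 7578 in WT. This class exceeded the mean of its neighbours 3.195 times in Irx5KO and 3.181 times in WT, which restates the pattern and decides no cause. Broad accessible domains centred on gene ends are argued against by the gene-end share, by midpoint, of at most 0.182% in this class. A peak this wide that starts at a gene end has its midpoint outside the 1000 bp window. Domains of that kind could not be counted and stay open. Full-length repeat copies that collect multiply mapped reads stay open, as repeat annotation was not used here, and since both genotypes show the pattern, no biological explanation was tested.

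The third pattern was regions covered far more in 1 list. Outside Dock2, 815 kb of the segments on chromosomes 5, 8 and X lay over 5 kb from any gene. Accessible chromatin at genes alone does not cover that part, but the segments had been seen when this test was chosen. In the Pramel cluster of chromosome 5 (93 to 96 Mb) opening of the genes only is argued against. Coverage there was 1.189 times higher in Irx5KO over 5 kb from genes, and 1.098 times higher within genes. Extra copies in the mice of 1 genotype would give sharp borders, and the flanks differed by at most 3.68 points, but that is also what a stretch without usable signal in 1 list, bridged by the peak calling in the other, would give. In the Dock2 segment the Irx5KO list held 0.0561 times the peaks expected from its flanks, but this was known when the test was chosen and decides no cause; the other list held 2 peaks against 91.7 expected on chromosome 8 and 4 against 57.4 on chromosome 5, but 2 against 0.702 on chromosome X, where the flanks were almost fully covered. Extra copies alone would leave the other list near its flank level, but at Dock2 and on chromosomes 8 and 5 it lay far below. In both lists the smallest gap between neighbouring peaks was 40 bp, which argues against a bridge by distance alone. The settings of the peak calling are not given, so another kind of bridge stays open. Without read depth, copy number, a deletion included, cannot be told apart from it. In the Pramel cluster coverage near its ceiling keeps the copy number open.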

How the results depend on the processing

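The alternatives with peaks up to 2000 bp wide, with the WT list limited to the Irx5KO number of peaks, with added matching and without Tcf7l1 were chosen after seeing the data. Not run were the ranking by −log10 p (the column holds 0), motif content, exons and introns, and leaving out replicates. No paired analysis was possible because the lists pool both replicates of a genotype. Read depth was not given, so its effect could not be computed. The ratio of peak numbers kept its value under both alternatives run.

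The HFSC identity list kept its call in 8 of 9 alternatives (percentiles 99.84 to 100) and lost it in the upper 50% by score (71.97, from 7 and 6 peaks, so few peaks remained). Among the 50000 highest-scored peaks its genes had no genotype-only peak. Over all lists 120 percentiles kept their side of the limits, 7 fell back and 1 passed, for housekeeping genes under the 50% overlap (97.7).

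In the following pairs Irx5KO stands first, then WT. The rules alone fix the direction of some changes. A 50% overlap rule can only lower the shared share, and counting peaks within 500 bp can only raise it. Equal list lengths shorten the WT list alone and can only lower the Irx5KO shared share. The width limit takes wide peaks out of both lists, so a narrow peak inside a wide peak of the other list can become genotype-only. Score thresholds can only lower the receptor shares and the peak numbers at Irx5, and a wider window can only raise the receptor shares. For the other changes, where no construction is named, the cause was not tested. The shared share was 96.5% and 95.4% in the upper 50% by score, 99.8% and 99.9% among the 50000 highest-scored peaks, 77.45% and 73.0% on autosomes, 76.25% and 71.4% with 50% overlap, 84.1% and 80.8% with peaks within 500 bp counted, 71.9% and 69.2% with peaks up to 2000 bp, and 77.9% and 75.1% with equal list lengths. The gene-end share of genotype-only peaks was 1.73% and 1.46% in the upper 50%, 0.943% and 5.09% among the 50000, 4.73% and 3.25% with 50% overlap, 3.79% and 2.37% with 500 bp, 11.2% and 7.84% in the 3000 bp window, which is wider by construction, and 4.14% and 3.11% with peaks up to 2000 bp. Receptor genes with a gene-end peak were 28.0% and 31.5% in the upper 50%, 4.72% and 4.85% among the 50000, and 85.65% and 89.2% in the 3000 bp window. Peaks at Irx5 numbered 3 and 3 in the upper 50% and 1 and 0 among the 50000. Genes with a gene-end peak in 1 genotype only were 2584 and 576 in the upper 50%, 179 for WT among the 50000 (1056 for Irx5KO), and 786 and 542 in the 3000 bp window. Under the score thresholds, the other list can hold a peak of such a gene below the threshold.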

Other observations

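The symbol families below and the 5 Mb region were chosen after the lists were seen; both tests on the Irx5 region were set before their own values were seen, the one with like score rank after the value of the other was known.

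Gene families with a common symbol stem were ranked by their Irx5KO-only share, with no list fixed in advance and no test. Families with at least 10 genes and at least 50 genotype-only peaks were used. Of these 211 families, the 5 with the highest shares were Arid with 71.2% (59.4 to 80.7) from 47 Irx5KO-only and 19 WT-only peaks, Tcf with 70.8% (61.1 to 79.0) from 68 and 28, Rassf with 70% (57.5 to 80.1) from 42 and 18, Armc with 66.7% (54.4 to 77.05) from 42 and 21, and the keratin genes (Krt) with 66.4% (57.4 to 74.3) from 77 and 39. The Tcf family includes Tcf7l1 and Tcf7l2 of the HFSC identity list, and the keratin family its Krt5, Krt14 and Krt15, so these shares are not independent of that list.

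The 5 families with the lowest shares were Esp, which encodes pheromone peptides, with 25.65% (19.98 to 32.3) from 49 and 142 peaks, the Klra receptors of natural killer cells with 29.2% (22.1 to 37.6) from 38 and 92, the Sult sulfotransferases with 30.8% (25.3 to 36.9) from 74 and 166, the Scgb secretoglobins with 31.5% (25.1 to 38.6) from 56 and 122, and the Prl prolactin family with 31.8% (23.7 to 41.1) from 34 and 73. Reads shared between similar neighbouring copies could make these counts uncertain, which was not tested.

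As a hypothesis, DNA of another strain around a targeted allele could raise the number of genotype-only peaks near Irx5. Within 5 Mb of Irx5, 34.7% of 2842 peaks were listed in 1 genotype only (440 in Irx5KO and 547 in WT), against a median of 24.6% over 2441 overlapping windows of 10 Mb, at percentile 97.54. Among 244 windows of like median score rank the percentile was 96.72, with a median of 27.7%. The 2 values lie on either side of the limit for a call, so flanking DNA of another strain and the low scores of peaks in this region both stay open.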
